A study of Mus musculus with 10 samples.

How the data were processed

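Genomic DNA of leukaemic mouse spleen cells was profiled by reduced representation bisulfite sequencing in 10 libraries of 4 groups. Per the labels' protocols, 0.3 to 1 µg of DNA was cut with MspI, inserts of 40 to 280 bp were selected on a gel, bisulfite conversion used a commercial kit, and libraries were run with 45% PhiX on an Illumina HiScanSQ. Per the submitters' processing notes, the tools were CASAVA, Trim Galore 0.2.2, Bismark 0.7.4 and methylKit, and the build was mm9; their settings are not given in the sources used here. Each deposited file lists, per CpG, a pair of whole numbers, read here as counts of methylated and unmethylated reads. The order was settled from the values: mitochondrial CpGs, which serve as a guide to unconverted cytosines, read as methylated in 0.910 to 3.20% of calls. Positions within a file were never closer than 2 bp, as for CpGs with both strands joined.

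Groups were taken from the oncogene and knockin labels. Replicates were numbered within groups and pair no samples. The highest correlation of CpG levels within a group was 0.969, and no 2 libraries were treated as 1. CpGs entered a comparison with at least 10 reads in every library of that comparison, on the 19 autosomes, since Y-linked reads differed between libraries of 1 group.

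Mean methylation weighted each CpG once and was tested by exact two-sided permutation, within oncogene where both models entered. CpGs were also split by mean level over the libraries of the comparison (under 20, 20 to 80 and over 80%) and by the CpGs listed in their 1-kb window (under 20, 20 to 59, 60 or more). The bounds of density and a class under 5% were chosen after the data were examined. The difference between models was tested by permuting oncogene labels within genotype. All arrangements were used, but the p is exact only if the models are alike apart from the knockin effect. Reads were summed in 1000-bp windows with at least 3 CpGs and fitted with a quasi-binomial logistic model. Its dispersion was moderated with limma 3.58.1 in R 4.3.3 and held at 1 or above, followed by an F-test and Benjamini-Hochberg adjustment. A call needed an adjusted p under 0.05 and a difference of at least 10 points. Each model was fitted apart, the interaction used all 10 libraries, and the comparison of WT leukaemias used the 5 WT libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the rest.

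The fits were tested on simulated counts drawn for the real windows, with 200 windows changed by each of 3 sizes. In MLL-AF9 the fit recovered 5.5% of windows changed by 20 points, 17.5% by 40 and 34.5% by 60, and 0.862% of its calls were false. In cMyc-Bcl2 it recovered 0% at 20, 40 and 60 points. The additive fit of both models recovered 57.5%, 88.5% and 100% and 8.04% of its calls were false. Of unchanged windows, 8.11% in MLL-AF9, 7.40% in cMyc-Bcl2 and 14.5% in the additive fit had an unadjusted p under 0.05, so unadjusted counts are too high.

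Windows were named by a rule set before the data were examined: per model, the 3 largest gains and 2 largest losses among called windows whose libraries do not overlap between genotypes, and 5 each way between WT leukaemias. Its part on 6 promoters called in both models was applied to windows of the additive fit, after the data were examined. The alternatives set beforehand were coverage minimums of 20 and 5 reads, weighting by reads, 500-bp windows, single CpGs, other thresholds, limma on M-values with 0.5 added (also centred), Fisher's exact test on pooled reads, the 4 groups in one fit, chromosomes X and Y, leaving out chromosomes 6 and 11, a limit at the 99.9th percentile of coverage, and leaving out each library. Alternatives added later were common weights, leaving out chromosomes 15, 16 and 17, 2 trended dispersions, the additive fit and a classing of CpGs by the WT libraries of the other model.

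The gene table used here is of another build, GRCm38, and no genome was used, so no region was given a gene name. Promoters, gene bodies, the 14 gene lists fixed beforehand, read depth over introduced genes and Dnmt3b itself were not analysed here, and neither were single strands. The knockin label therefore has no check from Dnmt3b. Read counts are not independent molecules, so depth covers counting error only.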

Results

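DNA methylation was measured by reduced representation bisulfite sequencing in 10 mouse leukaemia libraries. In this assay MspI-cut, CpG-rich fragments are bisulfite converted, so that an unmethylated cytosine is read as thymine. MLL-AF9 is a fusion oncoprotein of acute leukaemia, and MLL-AF9 leukaemia was represented by c-kit+ leukaemic spleen cells, 3 WT and 3 Dnmt3b-knockin libraries. The other model was driven by cMyc and Bcl2, a transcription factor and an inhibitor of apoptosis, and gave leukaemic spleen cells of 2 WT and 2 knockin libraries. Dnmt3b is a de novo DNA methyltransferase. Each comparison of knockin with WT asks whether methylation differed between leukaemias with and without the Dnmt3b knockin. Libraries held 14446933 to 46762220 CpG read calls and 569606 to 1148309 CpGs with at least 10 reads. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these libraries. That spread may be technical in MLL-AF9 WT and between MLL-AF9 knockin replicates 2 and 3. Relative chromosome depth differed between the libraries of both cMyc-Bcl2 groups and set MLL-AF9 knockin replicate 1 apart. That of chromosome 15 was 1.14 and 0.879 in cMyc-Bcl2 WT, and that of chromosome 16 was 1.22 and 0.981 in cMyc-Bcl2 knockin. That of chromosome X was 0.645 in MLL-AF9 knockin replicate 1, against 1.04 and 1.03 in replicates 2 and 3. Replicate 1 also held 1764 read calls on chromosome Y, against 125 and 97 in replicates 2 and 3 and 24 to 48 in MLL-AF9 WT. In cMyc-Bcl2 WT these calls numbered 195 in replicate 1 and 1493 in replicate 2. Comparisons did not take sex into account, apart from the limit to autosomes.

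In MLL-AF9 leukaemia, mean methylation was 16.6% ± 0.450 (SD, n = 3) in WT and 18.6% ± 0.692 (SD, n = 3) in knockin libraries. Each knockin library lay above each WT library: the knockin values were 19.1%, 18.9% and 17.8%, and the highest WT value was 17.1%. The difference of 2.03 percentage points was taken over 379839 autosomal CpGs with at least 10 reads in all 6 libraries. The exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 libraries allow. The difference was 0.601 points over CpGs with at least 20 reads (exact permutation p = 0.1). When CpGs were weighted by each library's own reads it was 3.20 points, but p was no longer the smallest possible (exact permutation p = 0.2).

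In cMyc-Bcl2 leukaemia, mean methylation was 27.9% ± 0.358 (SD, n = 2) in WT and 30.9% ± 0.873 (SD, n = 2) in knockin libraries, a difference of 3.04 points over 700113 CpGs. Both knockin libraries, at 31.5% and 30.3%, lay above both WT libraries, at 28.1% and 27.6%. The exact two-sided permutation p was 0.333, the smallest that 2 against 2 libraries allow. When each library's CpGs were weighted by its own reads, the direction turned, to -2.45 points (exact permutation p = 1.0); with 1 common set of weights for the libraries it was 2.79 points.

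Over the 274639 CpGs covered in all 10 libraries, the mean of the within-model differences was 2.35 points. Knockin exceeded WT in both models, by 2.11 points in MLL-AF9 and 2.58 points in cMyc-Bcl2. With genotype permuted within oncogene, the exact two-sided p was 0.0167, the smallest that the 120 arrangements can give. Over CpGs with at least 20 reads the difference was 0.728 points (exact permutation p = 0.0167). Weighted by each library's own reads, it was 0.519 points and no longer passed (exact permutation p = 0.817).

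**Figure D1:**
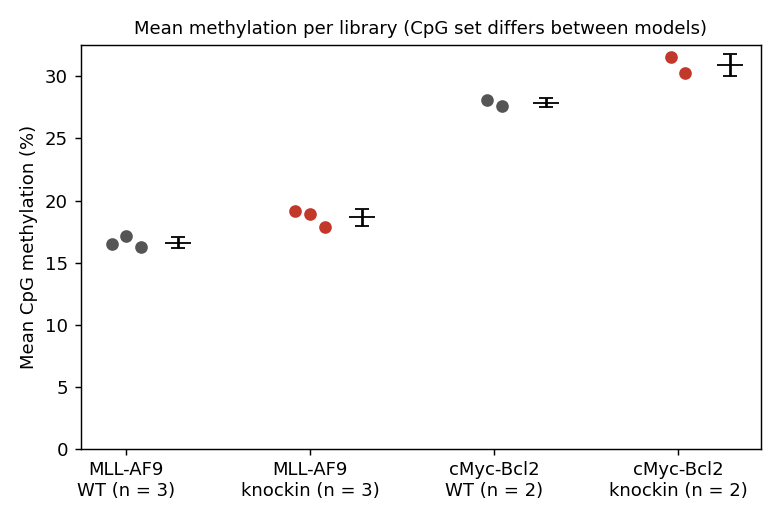
Mean CpG methylation in percent (y axis) for each library (points) in the 4 groups (x axis), with the group mean and SD beside the points; the CpG set differs between the models. Knockin libraries lie above the WT libraries of their model, at 18.6% against 16.6% on average in MLL-AF9 and at 30.9% against 27.9% in cMyc-Bcl2.

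In percentage points, CpGs of intermediate level differed more than those of low level. When CpGs were classed by the WT libraries of the other model, which take no part in the difference, those at 20 to 80% were at 45.5% ± 2.72 in WT and 55.4% ± 3.27 in knockin libraries of MLL-AF9 (SD, n = 3 each), a difference of 9.83 points. In cMyc-Bcl2 they were at 48.3% ± 0.102 and 60.3% ± 2.87 (SD, n = 2 each), a difference of 11.9 points. CpGs under 5% by the same classing differed by 0.559 points in MLL-AF9 and 1.03 points in cMyc-Bcl2. The exact permutation p was 0.1 in MLL-AF9 and 0.333 in cMyc-Bcl2 for each, the smallest possible. The class under 5% went from 1.33% in WT to 1.89% in knockin libraries of MLL-AF9 and from 1.66% to 2.69% in cMyc-Bcl2. Relative to the WT level, that rise was larger than the rise at 20 to 80%, so the contrast depends on the scale. CpGs over 80% by this classing differed by 3.27 points in MLL-AF9 (exact permutation p = 0.1). In cMyc-Bcl2 they were at 91.7% ± 0.122 in WT and 92.2% ± 1.04 in knockin libraries (SD, n = 2 each; exact permutation p = 1.0), and 1 of the 2 knockin libraries lay below the WT mean. This classing was added after the data were examined. Classed instead by the mean over the libraries compared, CpGs with a mean level of 20 to 80% rose in MLL-AF9 from 39.8% ± 3.91 (SD, n = 3) to 53.2% ± 4.74 (SD, n = 3), and in cMyc-Bcl2 from 39.1% ± 0.555 (SD, n = 2) to 55.4% ± 3.48 (SD, n = 2). Over the CpGs common to both models this class differed by 14.3 points (24940 CpGs; exact permutation p = 0.0167). CpGs under 20% differed by 1.08 points (exact permutation p = 0.0167) and those over 80% by 1.58 points (exact permutation p = 0.0333), with 2.64 points in MLL-AF9 and 0.521 in cMyc-Bcl2. Because the knockin libraries enter that mean, a CpG that changes much falls into the intermediate class, so part of the contrast between these classes comes from the classing. The classes overlap, and their p-values belong to a family of 17, in which the adjusted value of the intermediate class was 0.0258 by Benjamini-Hochberg from the exact permutation test.

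Within the intermediate class, over the CpGs of all 10 libraries, the difference was also computed by CpG density. In cMyc-Bcl2 the difference was 25.3 points in 1-kb windows with 60 or more listed CpGs, 17.1 points in windows with 20 to 59, and 7.05 points in windows with under 20. In MLL-AF9 the order was the other way, with 8.67, 13.7 and 14.1 points. The difference between the models in the CpG-dense class was -16.7 points (MLL-AF9 minus cMyc-Bcl2; exact permutation p = 0.09), and it did not pass after adjustment over 17 classes (Benjamini-Hochberg adjusted exact permutation p = 0.283). None of the 17 classes passed. The test had 100 arrangements, too few for 1 class alone to pass after this adjustment. It also takes the models to be alike apart from the knockin effect.

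**Figure D2:**
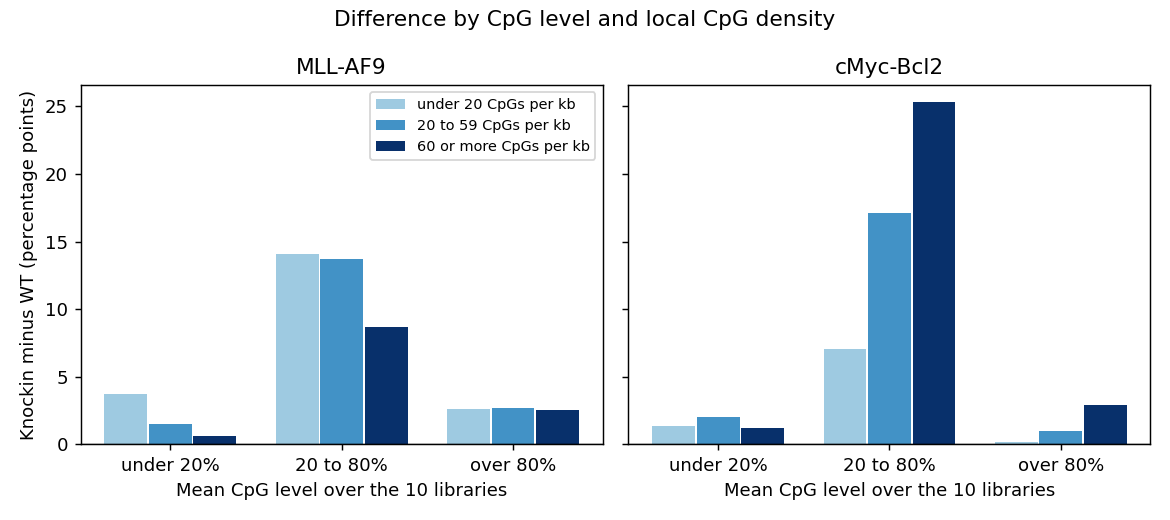
Knockin minus WT difference in percentage points (y axis) by the mean level of CpGs over the 10 libraries (x axis) and by the number of CpGs listed in the 1-kb window (bar shade), in MLL-AF9 and cMyc-Bcl2; bars are differences of group means. The largest bar is the CpG-dense intermediate class of cMyc-Bcl2, at 25.3 points, where MLL-AF9 differed by 8.67 points. The libraries compared enter the mean that sets the classes, so part of the contrasts may come from the classing.

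In MLL-AF9 leukaemia, 13 of 27129 windows gained methylation with the knockin and 1 lost it, at an adjusted p under 0.05 from the quasi-binomial fit with limma's moderated dispersion and a difference of at least 10 points. The largest gain lay on mm9 chromosome 2 at 69509044 to 69509121, where 9 CpGs went from 14.7% ± 8.07 (SD, n = 3) to 80.3% ± 7.82 (SD, n = 3; limma-moderated adjusted p = 0.0429), with 152 to 292 reads per library. On chromosome 5 at 110860950 to 110860987, 3 CpGs went from 11.2% ± 6.47 to 72.3% ± 2.73 (SD, n = 3 each; limma-moderated adjusted p = 0.0421), with 41 to 90 reads per library. On chromosome 9 at 65377676 to 65377699, 3 CpGs went from 14.9% ± 2.40 to 72.1% ± 4.05 (SD, n = 3 each; limma-moderated adjusted p = 0.0321), with 50 to 99 reads per library. The lost window lay on chromosome 6 at 67485418 to 67485472, where 12 CpGs fell from 52.2% ± 6.60 to 3.93% ± 1.77 (SD, n = 3 each; limma-moderated adjusted p = 0.0321). Whether these regions lie in genes, exons or introns was not analysed here. Leaving out any 1 of the 6 libraries ended each of these calls, while the pooled differences stayed at 63.1 to 71.2, 53.0 to 64.4, 55.5 to 59.7 and -52.4 to -43.9 points for the windows on chromosomes 2, 5, 9 and 6, and limma on M-values called 0 windows each way, with 3692 at an unadjusted p under 0.05.

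Windows in which every knockin library lay above every WT library by a mean of at least 10 points numbered 1911 in MLL-AF9, against 42 the other way. Without a minimum difference they were 5101 and 375, or 18.8% and 1.38% of windows, where chance gives 5% each way for a single window. With at least 10 points, the most that another split of the 6 libraries gave one way was 707, with 61 the other way. In cMyc-Bcl2, windows without overlap and with at least 10 points numbered 6950 higher and 1551 lower; without a minimum they were 24.1% and 17.6% of windows, where chance gives 16.7% each way. Both counts were added after the data were examined.

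In cMyc-Bcl2 leukaemia, 1 of 54108 windows gained and 0 lost methylation in the same quasi-binomial fit, with 7130 at an unadjusted p under 0.05, of which 5968 were higher in knockin. The gained window lay on mm9 chromosome 8 at 113494083 to 113494551, where 15 CpGs went from 3.48% ± 0.146 (SD, n = 2) to 96.8% ± 0.420 (SD, n = 2; limma-moderated adjusted p = 0.0303), with 412 to 828 reads per library. limma on M-values called 1 gained and 0 lost windows, with 6116 at an unadjusted p under 0.05, and leaving out any 1 of the 4 libraries ended the call of the quasi-binomial fit, with the difference at 93.1 to 93.6 points. On simulated counts for these windows the fit recovered 0 of 200 windows changed by 60 points. This fit thus did not detect changes of that size with the simulated spread, which was set from windows of intermediate level and given to every window. The median dispersion of the real windows was 2.58. With a dispersion trend on level, a variant that was not simulated, the same 4 libraries gave 202 gained windows. The simulation therefore cannot say what 2 against 2 libraries can detect with another fit or spread. With the 4 groups in one fit, 1318 gained and 129 lost windows were called in cMyc-Bcl2, and 0 and 1 in MLL-AF9.

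No gained window was shared: 12 of the windows called in MLL-AF9 were also tested in cMyc-Bcl2, and none of these 24722 common windows was called there, which leaves the overlap test empty (one-sided Fisher's exact p = 1). Of those 12, 6 were higher in cMyc-Bcl2 knockin, 5 of them by at least 10 points, as were 4024 of the 24722 common windows. Windows at least 10 points higher numbered 2616 in MLL-AF9 and 4024 in cMyc-Bcl2, of which 1243 were shared, where independent lists would share 426, a value that takes no account of windows of intermediate level reaching 10 points more easily in either model. A further 346 windows differed by at least 10 points in opposite directions, and 21 were lower by as much in both. Window differences correlated between models with Pearson's r of 0.229 and Spearman's rho of 0.199, across windows, which are not independent replicates.

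One fit of all 10 libraries with oncogene and genotype as additive terms was added after the data were examined. It called 833 gained and 6 lost windows of 22907. Of the gained windows, 830 were higher in knockin in both models, which the selection for a common effect favours. In 538 of the 833, the libraries of the genotypes did not overlap in either model. The largest gain with no overlap in either model was on mm9 chromosome 4 at 155027481 to 155027512. There 4 CpGs went from 17.3% ± 12.5 to 69.9% ± 18.99 in MLL-AF9 (SD, n = 3 each) and from 9.87% ± 1.19 to 63.0% ± 6.81 in cMyc-Bcl2 (SD, n = 2 each; limma-moderated adjusted p = 0.00681). On chromosome 4 at 130185238 to 130185306, 5 CpGs went from 5.24% ± 6.04 to 47.1% ± 14.5 in MLL-AF9 (SD, n = 3 each) and from 5.61% ± 1.19 to 56.2% ± 18.2 in cMyc-Bcl2 (SD, n = 2 each; limma-moderated adjusted p = 0.00701). The other 4 windows with the largest gains, on chromosomes 12, 6, 10 and 8, differed by 31.4 to 48.6 points in MLL-AF9 and 48.4 to 64.2 points in cMyc-Bcl2. Among the losses, the window on chromosome 11 at 88181429 to 88181523 was the 1 that did not overlap in either model, falling from 95.6% ± 2.89 to 76.8% ± 3.95 in MLL-AF9 (SD, n = 3 each) and from 97.1% ± 2.09 to 81.1% ± 6.25 in cMyc-Bcl2 (SD, n = 2 each; limma-moderated adjusted p = 0.0126). It was singled out after its values were seen, and it lies in a stretch where read depth in some windows also separated the genotypes. In the other lost windows MLL-AF9 differed by -8.10 to 1.83 points, against -38.2 to -25.6 points in cMyc-Bcl2, so they are not losses common to both models. The count depended on the test and on single libraries: limma on M-values called 24 gained and 0 lost, with 3548 at an unadjusted p under 0.05, and the additive fit called 90 gained windows without cMyc-Bcl2 WT replicate 2, 542 without cMyc-Bcl2 knockin replicate 1, 511 without MLL-AF9 knockin replicate 1 and 490 without MLL-AF9 knockin replicate 2. On simulated counts 8.04% of the calls of this fit were false, above the nominal rate.

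The knockin effect differed between the models in 4 of 22907 windows by the interaction term, each with the higher knockin effect in cMyc-Bcl2. On mm9 chromosome 1 at 194677211 to 194677252, cMyc-Bcl2 rose from 16.8% ± 11.4 to 91.2% ± 4.72 (SD, n = 2 each), while MLL-AF9 was at 50.7% ± 6.18 in WT and 30.4% ± 7.59 in knockin libraries (SD, n = 3 each; limma-moderated adjusted p of the interaction = 0.0439). That window held 3 CpGs, with 32 to 189 reads per library. limma on M-values called 0, with 1978 at an unadjusted p under 0.05, and the count was 39 without cMyc-Bcl2 WT replicate 1, 24 without cMyc-Bcl2 knockin replicate 1, 9 without cMyc-Bcl2 knockin replicate 2, 1 without MLL-AF9 knockin replicate 2 and 0 without each of the others.

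The WT leukaemias of the 2 models differed in 40 of 25077 windows, 27 higher in cMyc-Bcl2 and 13 higher in MLL-AF9. This comparison describes the models without the knockin, and the oncogene cannot be separated from the c-kit sort. On mm9 chromosome 18 at 36651270 to 36651293, methylation was 4.51% ± 1.73 in MLL-AF9 (SD, n = 3) and 92.8% ± 1.54 in cMyc-Bcl2 (SD, n = 2; limma-moderated adjusted p = 0.0190), over 3 CpGs with 39 to 195 reads per library. The next 4 by size among those higher in cMyc-Bcl2, on chromosomes 15, 17, 8 and 9, lay at 86.0 to 96.6% on average in cMyc-Bcl2 and at 3.36 to 11.2% in MLL-AF9. On chromosome 9 at 110237783 to 110237854, methylation was 85.8% ± 8.16 in MLL-AF9 (SD, n = 3) and 14.4% ± 5.46 in cMyc-Bcl2 (SD, n = 2; limma-moderated adjusted p = 0.0443), over 3 CpGs with 51 to 209 reads per library. On chromosome 7 at 88021067 to 88021185, 9 CpGs were at 93.0% ± 1.53 in MLL-AF9 (SD, n = 3) and 22.6% ± 3.90 in cMyc-Bcl2 (SD, n = 2; limma-moderated adjusted p = 0.0190). limma on M-values called 23 and 7 windows, and no window was called when any 1 library was left out.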

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

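The tests of unconverted cytosines, of a strain haplotype, of CpG classes at 20 reads and of excess read depth windows given each split's total were chosen only after the result was seen, as were the additive fit and the counts of read depth, while leaving out chromosomes 6 and 11 was set beforehand and its bounds were written afterwards.

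The knockin effect differed between the models in 4 windows, given as MLL-AF9 minus cMyc-Bcl2 and each with a limma-moderated adjusted p of 0.0439, under the threshold of 0.05. The difference of the effects was -94.7 points in the window on chromosome 1 from 194677001, -66.6 on chromosome 6 from 64684001, -54.4 on chromosome 8 from 123598001 and -49.4 on chromosome 5 from 140017001. In each, cMyc-Bcl2 knockin libraries lay 40.1 to 74.4 points above WT, and leaving out 1 library gave 0 to 39 such windows. The relative read depth of chromosome 16 was 1.22 in cMyc-Bcl2 knockin replicate 1, where 185 of 190 values over autosomes and libraries lay between 0.9 and 1.1. The mean difference over both models was 2.38 points without chromosomes 15, 16 and 17.

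Mean methylation was higher in knockin libraries of both models. Incomplete bisulfite conversion as the whole cause would raise CpGs under 5% at least as much as those of 20 to 80%; classed by the WT libraries of the other model, the difference under 5% was at most 0.0865 times that at 20 to 80% in either model. Chromosomes 6 and 11, left out in case the knock-in or its reporter lies there, were not the source: without them the difference over both models was 2.33 points. The knockin itself and how deeply fragments are covered both stay open. With 1 common set of weights the difference in cMyc-Bcl2 was 2.79 points. A value above 1 point had been set beforehand as speaking against coverage, but how far these weights depart from equal weights was not measured. Each library's own weights gave -2.45 points in cMyc-Bcl2 and 0.519 over both models. At 20 reads the difference was 0.601 points in MLL-AF9 and 0.728 over both models; of the CpGs of all 10 libraries, those of 20 to 80% by cMyc-Bcl2 WT level made up 2.29%, against 8.22% at 10 reads, and still differed by 9.69 points in MLL-AF9.

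The window calls were counted again under other splits of the libraries. For MLL-AF9, the real split called 13 gained windows, and the highest of the others called 1; for losses these were 1 and 0. The real split was 1 of the 10 for each, and 10 splits are too few for a share under 0.05. For the additive fit, 1 of the 60 splits within oncogene, the real one, gave as many as 833 gained windows, and the highest other gave 252. A share of 1 of 60 lies under 0.05 and is the smallest possible. The fit was chosen after the higher knockin means had been seen, so the split count partly repeats that observation and does not by itself exclude chance. The fit called 90 gained windows without cMyc-Bcl2 WT replicate 2.

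Read depth separated the genotypes in 13 windows of a stretch on chromosome 11, at 85000001 to 100000000, in which 7 windows were higher and 6 lower in knockin libraries, of 73 such windows on the autosomes. By raw counts, the test chosen first, 6 of the 60 splits gave as many in some stretch, with 30 in the highest other split, but the totals of the other splits ran from 1 to 1065 windows. Given each split's total, the excess (-log10 of the hypergeometric tail) was 11.3 in the real split and 5.05 in the highest other. Thus 1 of the 60 splits, the real one, was as large, the smallest share possible. This score was chosen after the raw counts were seen, so chance is not excluded for the clustering. A gain or loss of the whole stretch is argued against by the median depth ratio of the knockin libraries, which was 0.953 at the lowest and 1.02 at the highest. A strain haplotype that travels with the knock-in may give such windows, but this is a hypothesis found in these data, and no variant was examined. On the whole of chromosome 11 their share was 4.03 times that on the other autosomes, with 8 higher and 10 lower. The excess there was 5.25, against 1.25 in the highest other split. Of these 18 windows, 13 lie in the stretch already found, so the values for the whole chromosome are not separate support.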

How the results depend on the processing

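Weights by mean coverage, chromosomes 15, 16 and 17 left out, the trended dispersions, the additive fit and the alternatives for intermediate CpGs were tested only after the result was seen. The mean difference in MLL-AF9 kept its direction in all 14 alternatives, at 0.601 to 3.20 points (1.78 to 2.40 when 1 library was left out), with an exact permutation p of 0.1 to 0.2. With at least 10 reads when classed by the WT libraries of the other model, the difference of the intermediate CpGs was 9.83 points in MLL-AF9 and 11.9 in cMyc-Bcl2. The same classing at 20 reads gave 9.69 and 9.81 points, the lowest values, over 734 and 687 CpGs. The highest values of the alternatives were 15.9 and 19.5 points. Both classings used the CpGs of all 10 libraries. Weighted by each library's own reads, the difference in cMyc-Bcl2 was -2.45 points and that over both models 0.519 points (exact permutation p = 0.817); with 1 common set of weights they were 2.79 and 2.25, so the turn came from weights that differ between libraries. Otherwise they lay at 2.39 to 3.81 and 0.728 to 2.61 points. The 13 gained windows of MLL-AF9 became 0 at 20 reads, 24 at 5 reads, 5 in 500-bp windows, 0 for single CpGs, 0 at 25 points and adjusted p 0.01, 0 with limma, 0 with centred limma, 3023 by Fisher's exact test on pooled reads, 0 in the fit of 4 groups, 5 with a trend on level and 0 with a trend on binomial variance, and were 0 to 0 when 1 library was left out. The 1 lost window became 0 at 20 reads, for single CpGs, at 25 points, with limma, with centred limma, without chromosomes 6 and 11 (where it lies) and with the trend on binomial variance, 2 with no minimum difference, 245 by Fisher's test and 0 to 0 when 1 library was left out. In cMyc-Bcl2 the 1 gained window became 0 in 500-bp windows, for single CpGs, at 25 points and with the trend on binomial variance, 202 with the trend on level, 1318 in the fit of 4 groups, 8621 by Fisher's test and 0 to 0 when 1 library was left out; losses went from 0 to 3 with the trend on level, 129 in the fit of 4 groups and 2299 by Fisher's test. Pooled reads ignore the spread between libraries. The 4 groups share 1 dispersion, with a median of 1.59 in MLL-AF9 and 2.15 in cMyc-Bcl2 on the same windows. That fit also tested 22907 windows, against 54108 in the fit of cMyc-Bcl2 alone, and drew its dispersion from all 10 libraries. Which of these changed the counts was not tested. The additive counts of 833 and 6 became 24 and 0 with limma, 31 and 0 at 20 reads, where 4019 windows were tested, and 90 to 993 and 2 to 12 when 1 library was left out. The interaction count of 4 became 0 at 20 reads, 0 with limma and 0 to 39 when 1 library was left out. The 40 windows between WT leukaemias became 0 at 20 reads and 0 to 0 when 1 library was left out. For the changes not given a reason here, the cause was not tested. The 5 windows named from the single-model fits kept their direction in all 42 values, and 8 of these kept the call. Leaving out 1 of 2 libraries of a group assumes that the lone library varies like the others. Single strands, promoters and gene lists were not run. The main fit, without a trended dispersion, recovered 0% of simulated changes of 60 points in cMyc-Bcl2, with a spread set from windows of intermediate level.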

Other observations

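The 200-kb bins and the test of neighbouring windows were chosen only after the result was seen.

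Levels were averaged over bins of 200 kb with at least 10 tested windows. In cMyc-Bcl2, 107 of 1661 bins gained at least 10 points and 0 lost as much. On mm9 chromosome 14 at 49200001 to 49400000, the mean was 24.0% ± 6.37 in WT and 50.9% ± 3.27 in knockin libraries (SD, n = 2 each). On chromosome 12 at 57600001 to 57800000, it was 13.6% ± 4.12 and 40.3% ± 0.0526 (SD, n = 2 each), with 15 of 15 windows higher. In MLL-AF9, 8 of 543 bins gained at least 10 points and 0 lost as much. On chromosome 5 at 122400001 to 122600000, the mean was 48.2% ± 3.23 in WT and 60.8% ± 2.27 in knockin libraries (SD, n = 3 each), and on chromosome 15 at 102600001 to 102800000 it was 7.34% ± 1.96 and 19.2% ± 5.11 (SD, n = 3 each). No test was applied to the bins, and none was given a gene name.

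A hypothesis is that gains in cMyc-Bcl2 may lie in domains that follow the knock-in. The differences of windows 5 to 50 kb apart correlated, across window pairs, with r of at least 0.00921 in each pair of a knockin and a WT library, against at most 0.00713 between libraries of 1 genotype. Over group means r was 0.0155, and the highest of 100 shuffles gave 0.00775. These values are close to 0, each genotype has 1 pair, and window pairs are not independent. In MLL-AF9 the values of the library pairs overlapped, at -0.000682 to 0.0175 against -0.00367 to 0.0106, while over group means r was 0.0186 and the highest shuffle gave 0.0111. No difference between the models was tested.

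Relative depth of chromosome 15 was 1.14 in cMyc-Bcl2 WT replicate 2, 0.879 in WT replicate 1 and 0.890 in knockin replicate 2.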
